A study of Mus musculus with 6 samples.

How the data were processed

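RNA from lenses of newborn mice was hybridised to one array per sample, 3 from Le-AP-2alpha conditional mutants and 3 from wild-type littermates. Per the labels, lenses were dissected, total RNA was isolated with a column kit, amplified with a Nugen Ovation system and labelled with biotin. The deposited values are intensities of probe sets, 1 column per array. RMA, a method that corrects background, normalises arrays by their quantiles and summarises the probes of a probe set, is named per the submitters' processing notes, with no version or settings. RMA commonly reports log2 values, whereas the deposited intensities are on a linear scale, with array medians of 36.52 to 40 and maxima of 15256 to 16087. What was done between the RMA step and the deposited scale is not given in the sources used here. Background correction and quantile normalisation can compress differences of dim probe sets and remove shifts common to a whole array, so probe sets below the median level are named as dim. Those of Maf, Tnc, Epcam, Itga2, Krt14, Krt1, Pecam1, Epb42, Alas2, Acta1, Tnnc2, Sp5, Egr2, Chac1, Uty and Xist are dim too and are not marked again at their values.

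The log2 of each deposited intensity was taken here, with no pseudocount and no further normalisation. Groups came from the labels, and 0 columns of sample values were left out. The arrays were checked for duplicates: the highest share of probe sets with equal values in a pair of arrays was 0.186%. Probe sets were named through the platform annotation of 2016: 20380 tested probe sets had 1 gene symbol, 691 had several and 1555 had none. Of the first, 20351 were matched by Entrez ID to a RefSeq gene table of the GRCm38.p6 assembly, which changed 0 symbols. Probe sets with several symbols were not used to name a gene. No genome build is given in the sources used here, so positions are not reported. A gene was represented by its probe set of highest mean over all arrays.

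Tests used R 4.3.3 and limma 3.58.1. Each probe set was fitted with lmFit and eBayes on the log2 scale, mutant against wild type, with no covariate, and two-sided p-values were adjusted by Benjamini-Hochberg over all 22626 tested probe sets, with a threshold of 0.05. Differences are given as mutant minus wild type with the standard error of the fit; levels are mean ± SD. Gene lists were tested with limma's camera, which compares a list with all other genes, with a preset correlation of 0.01 between genes, adjusted over 27 lists. The same test with a correlation estimated from the residuals, and the rotation test fry, which asks whether a list's genes move one way on balance, were run beside it. Members were also adjusted over the list alone. The lists held 426 entries, of which 379 were measured, and covered crystallins, other fibre cell genes, lens epithelium, the AP-2 family, capsule and basement membrane, epithelial to mesenchymal transition, epithelial junctions, integrins, signalling and stress pathways, cell division and DNA replication, sex-linked genes, and markers of neighbouring tissues and blood cells.

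The groups, tests, lists, alternatives and the rule for named genes were set before the data were examined. The rule took the largest rises and falls among genes past the threshold or, where fewer than 5 passed in a direction, the 10 genes of lowest p in that direction, given as values, leaving out clone and model names. It also took the 2 members of lowest p from each list, or those past the threshold, and always the AP-2 family, Cdh1, Cdh2, Foxe3, Pax6, Prox1, Maf, Cryaa and sex-linked genes. The design had foreseen that values could be on a linear scale.

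The fit was tested on simulated data over 22626 probe sets with the spread of all 6 arrays, in which 50 probe sets each were changed by a log2 of 1, 2, 3 or 4. It recovered 12%, 48%, 90% and 86% of them, with 8 false calls. Noise was drawn independently for each probe set, with no array standing apart from the rest. These shares therefore need not hold for the real arrays.

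Alternatives were the replicate number as a block, median centring, quantile normalisation, leaving out dim probe sets, a trended prior, array weights, leaving out each array, a minimum fold of 1.5, a threshold of 0.1, the mean of a gene's probe sets, an estimated correlation and fry. Added after seeing the data were leaving out wild-type replicate 1 and mutant replicate 2 together, and the 3' to 5' difference of control probe sets as a covariate. In comparing alternatives, a gene's difference within 1 standard error of 0 was treated as having no direction. The labels give no scan dates or batches. Lists of neuronal genes and of neural retina genes were chosen after seeing the data and are used only among the closing observations.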

Results

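Gene expression was measured in lenses of newborn mice with a one-colour oligonucleotide array on which biotin-labelled material from total RNA was hybridised. Lenses of Le-AP-2alpha conditional mutants, in which the transcription factor gene Tfap2a (older symbol Tcfap2a) is targeted, were compared with lenses of wild-type littermates, 3 arrays per group and 6 in all. The title of the series places the comparison within the question of what AP-2alpha does in the lens itself, including whether the lens epithelium keeps its character. Each array reported 22690 probe sets, of which 64 were array controls and 22626 were tested, and 12393 genes were represented by their brightest probe set. The median log2 level per array lay between 5.19 and 5.32. Wild-type replicate 1 stood apart from the rest, with Pearson correlations across probe sets of 0.926 to 0.945 with the other arrays, against 0.974 to 0.985 among those 5. The labels do not say whether a sample is 1 animal or a pool, so p-values measure the spread between these samples, and the number of arrays limits the precision.

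Tfap2a signal was not lower in the mutant lenses. Its brightest probe set had a log2 level of 9.68 ± 0.13 (SD, n = 3) in mutants and 9.06 ± 0.63 in wild types, with individual mutants at 9.57, 9.64 and 9.83 and individual wild types at 8.36, 9.26 and 9.56. The difference was 0.62 ± 0.33 (SE), and without wild-type replicate 1 it was 0.27. The other Tfap2a probe sets differed by 1.57 ± 0.49 and 0.36 ± 0.36, and all of them had a limma adjusted p of 0.999. The labels do not say which part of the gene was deleted and the positions of the probes are not known here, so these values do not check the deletion. Whether RNA of other cells carried over with the lens added to the signal of Tfap2a or of the other AP-2 genes was not tested.

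The other AP-2 family members, which bind related DNA sites, also had higher values in the mutants. Tfap2b was at 7.30 ± 0.48 in mutants and 5.46 ± 1.31 in wild types (SD, n = 3), a log2 difference of 1.84 ± 0.65 (SE), and Tfap2c at 8.52 ± 0.47 and 7.03 ± 1.36, a difference of 1.49 ± 0.67. Without wild-type replicate 1 the differences were 1.08 for Tfap2b and 0.72 for Tfap2c. Tfap2d, which was dimmer than the median probe set, differed by 0.83 ± 0.41. As a list the 4 measured AP-2 genes rose, with a mean log2 difference of 1.19, all 4 higher, and a limma camera adjusted p of 0.000775 with a preset correlation between genes; the adjusted p was 0.374 with an estimated correlation. No member passed over all genes tested (0) or adjusted over the list alone (0). Wild-type replicate 1 had the lowest list mean, 5.37 against 6.78 and 6.76 in the other wild types, and without it the list's mean difference was 0.73, with an adjusted p of 0.00478.

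**Figure D1:**
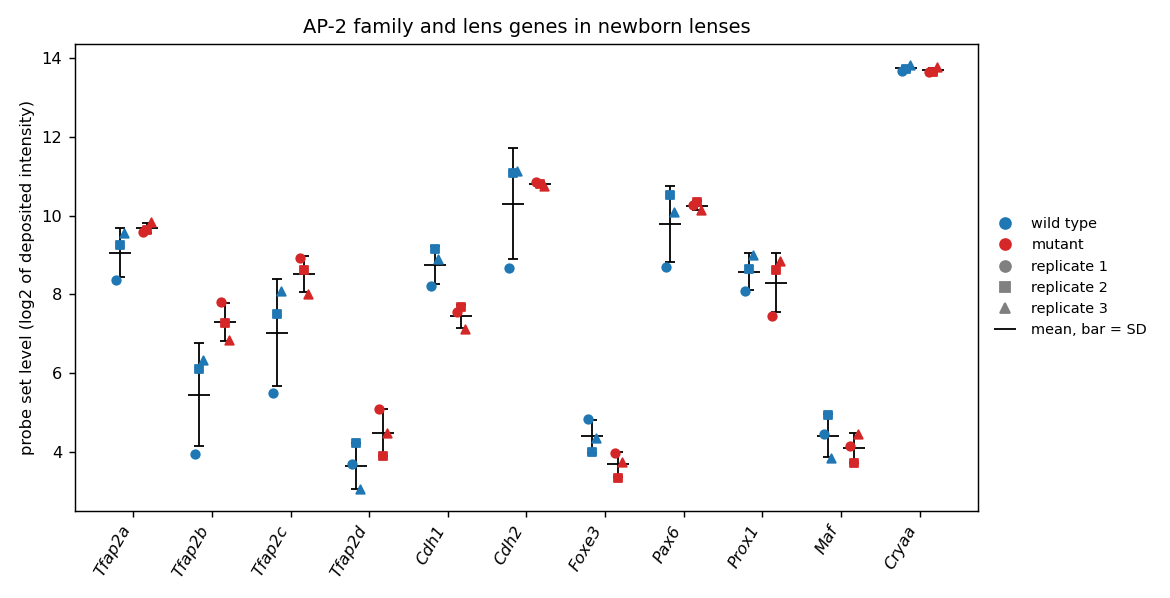
Log2 probe set level (vertical axis, log2 of the deposited intensity) of AP-2 family and lens genes (horizontal axis) in 3 wild-type and 3 mutant lens arrays, with 1 point per array, marker shape for the replicate number, a line at the group mean and bars of 1 SD. Each mutant point of Cdh1 lies below each wild-type point, with means of 7.45 and 8.75, and Cryaa lies near 13.7 in both groups, while wild-type replicate 1 is the lowest point for Tfap2b, Tfap2c, Cdh2 and Pax6.

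Of the single genes with higher values in mutants, Mapk8ip2 had the lowest p. Mapk8ip2, a scaffold protein of the JNK pathway that is abundant in brain, was 2.65-fold higher in mutants, at 7.88 ± 0.18 against 6.47 ± 0.11 (log2, SD, n = 3). Septin3, a neuronal septin, differed by 1.47 ± 0.21 (log2, SE), Scg3, a granin of secretory granules, by 1.33 ± 0.21, Rims2, a protein of the presynaptic active zone, by 1.60 ± 0.28, and Cplx1, a regulator of synaptic vesicle fusion, by 1.5 ± 0.26. The collagen VI chain Col6a1 differed by 1.27 ± 0.20 and the fatty acid desaturase Scd1 by 1.90 ± 0.33. The T cell receptor component Cd3g (1.06 ± 0.17), Gpnmb (1.05 ± 0.18) and the transcription factor Olig2 (1.04 ± 0.18) were dimmer than the median probe set, as was Cplx1. Other probe sets of Mapk8ip2, both dim, differed by 0.56 ± 0.27 and 0.14 ± 0.16. Of the other probe sets of Cplx1, both dim, one differed by 1.45 ± 0.43 and one by -0.16 ± 0.20, and a second, dim probe set of Scd1 differed by 0.03 ± 0.17.

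Of the genes with lower values in mutants, Pygl and Olfml3 had the lowest p. Olfml3, a secreted olfactomedin-like protein, was 8.05-fold lower in mutants, at 4.29 ± 0.08 against 7.29 ± 0.63, and Pygl, the liver form of glycogen phosphorylase, was 4.65-fold lower, at 5.21 ± 0.19 against 7.42 ± 0.21. Anxa1, a calcium-dependent phospholipid-binding protein, was at 8.67 ± 0.41 in mutants and 10.85 ± 0.44 in wild types. The glutathione transferases Gstm2 and Gstm1 differed by -2.45 ± 0.37 and -1.73 ± 0.33 (log2, SE); they are close relatives, and their probe sets can share signal. Myo5b, a motor of membrane recycling, differed by -1.79 ± 0.32, and Cpt1a, which carries fatty acids into mitochondria, by -1.12 ± 0.22. Col4a4, a basement membrane collagen chain, differed by -1.5 ± 0.17, Vmn1r51 by -1.57 ± 0.23 and Myl2 by -1.28 ± 0.21, all at levels dimmer than the median probe set.

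None of these genes passed the threshold. limma called 0 of 22626 probe sets and 0 of 12393 genes at an adjusted p under 0.05, and the lowest adjusted p was 0.15, reached by Pygl, by a probe set assigned to more than 1 gene (-2.84 ± 0.26) and by a probe set with no gene name here (2.21 ± 0.20). Adjusted p ran from 0.54 for Mapk8ip2 to 0.885 among the 10 higher genes and from 0.15 to 0.928 among the 10 lower genes. At an unadjusted p under 0.05 there were 742 probe sets, 385 higher and 357 lower, where 1131 would arise with no difference, and 477 genes, 264 higher and 213 lower. The groups did not overlap for 8.36% of probe sets and 8.8% of genes, against 10% by chance. With arrays weighted by limma, 7 probe sets passed at adjusted p of 0.0162 to 0.0302, among them those of Olfml3, Pygl, Anxa1, Gstm2 and Col4a4. The wild types had weights of 0.224 for replicate 1, 0.569 for replicate 2 and 5.65 for replicate 3. The wild-type mean thus rested mostly on replicate 3, and 3397 probe sets had an unadjusted p under 0.05. With wild-type replicate 1 left out instead, limma called 0 probe sets, with a lowest adjusted p of 0.107.

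**Figure D2:**
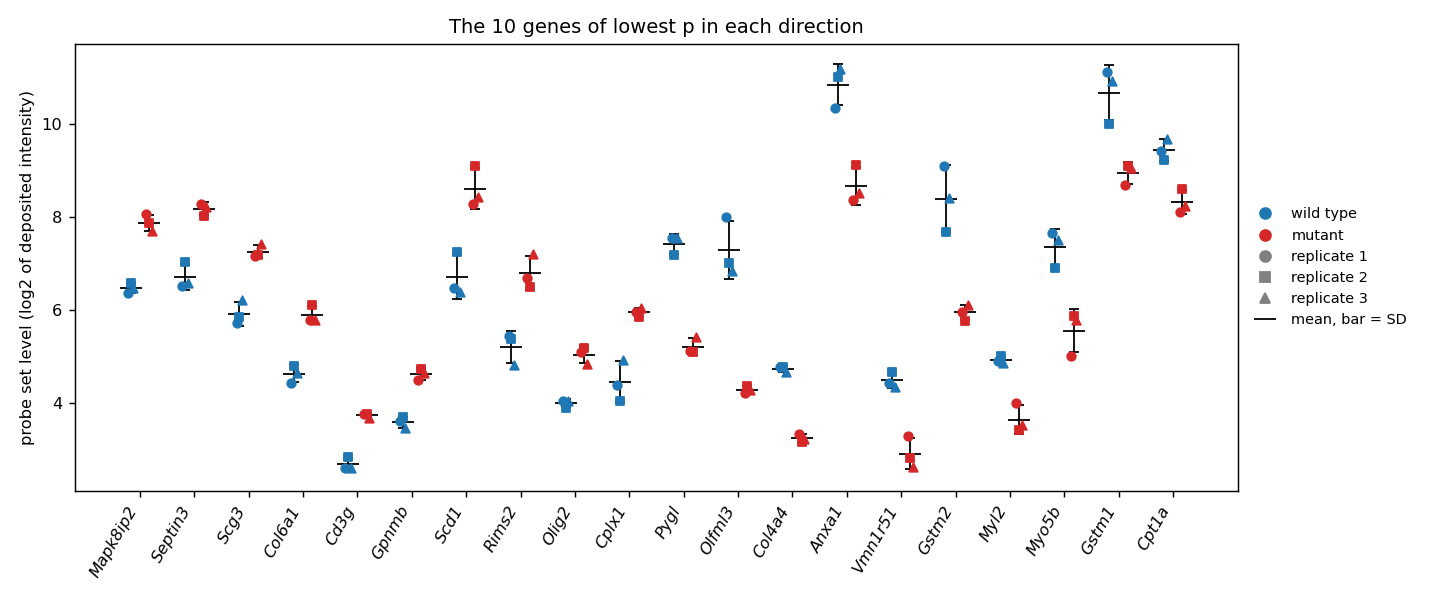
Log2 probe set level (vertical axis, log2 of the deposited intensity) of the 10 genes of lowest p that were higher and the 10 that were lower in mutants (horizontal axis), with 1 point per array, marker shape for the replicate number, a line at the group mean and bars of 1 SD. The genes were chosen by their p, so the separation of the groups is built into the choice, and 0 of them passed the adjusted threshold.

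Genes of the lens fibre cells and of the lens capsule were lower in the mutants as lists. The 20 measured genes of the capsule and basement membrane, which are collagen IV chains, laminins and their partners, fell by a mean log2 of 0.39, with 15 lower and 5 higher. The examples of lowest p were Col4a4 and the laminin chain Lama2, at 5.19 ± 0.33 in mutants and 6.45 ± 0.82 in wild types (SD, n = 3). The 14 measured fibre cell genes other than crystallins fell by a mean of 0.33, with 11 lower; Dnase2b, the nuclease that degrades DNA in maturing fibres, was at 8.39 ± 0.64 against 9.83 ± 0.55, and Bfsp1, a beaded filament protein, at 12.14 ± 0.20 against 12.79 ± 0.29. In the same list the transcription factors Prox1 and Maf differed by -0.28 ± 0.43 and -0.32 ± 0.34 (SE), and the cadherin Cdh2 by 0.50 ± 0.66, with -0.31 on the same probe set without wild-type replicate 1 and -0.18 ± 0.32 on its second probe set. Without mutant replicate 1 the difference of Prox1 was 0.14. limma camera gave an adjusted p of 0.00383 for the capsule list and 0.0133 for the fibre list with the preset correlation, and an adjusted p of 0.374 for both with an estimated correlation. Over all genes 0 members of either list passed; adjusted over the list alone, 1 capsule gene (Col4a4) and 0 fibre genes did. The call of the fibre list ended without wild-type replicate 2 (mean -0.30, adjusted p = 0.17) and without wild-type replicate 3 (mean -0.22, adjusted p = 0.0813).

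Crystallins, the main proteins of the lens, were measured near the top of the range in both groups. Cryaa was at 13.68 ± 0.08 in mutants and 13.73 ± 0.07 in wild types (log2, SD, n = 3). The 14 measured crystallins had a mean log2 difference of -0.15, each of the 14 with a lower value in mutants, and camera gave an adjusted p of 0.118, or 0.706 with an estimated correlation. The list was called with a trended prior (adjusted p = 0.0285), with array weights (mean -0.32, adjusted p = 0.00601) and with wild-type replicate 1 and mutant replicate 2 both left out (mean -0.29, adjusted p = 0.0347). The highest level on an array was 13.9 to 13.97, and 9 of the 14 crystallins had a mean level within 0.5 of it, where differences can be compressed, so these values limit what can be read from the size of the list's difference. Crygn (-0.44 ± 0.28, SE) and Cryab (-0.34 ± 0.23) had the lowest p.

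The epithelial cadherin Cdh1, a marker of the lens epithelium, was at 7.45 ± 0.29 in mutants and 8.75 ± 0.48 in wild types (log2, SD, n = 3), each mutant array below each wild-type array. Its difference of -1.29 ± 0.30 (SE) had a limma adjusted p of 0.999 over all probe sets. Foxe3, a transcription factor of lens epithelial cells, differed by -0.71 ± 0.29 at levels dimmer than the median probe set. The amino acid transporter Slc38a3 differed by -1.04 ± 0.40, and by -0.68 without wild-type replicate 1. Pax6, a transcription factor needed for eye formation, differed by 0.47 ± 0.47, and by -0.07 without wild-type replicate 1. The 17 lens epithelium genes had a mean difference of -0.16 but a median of 0.01, with 10 higher and 7 lower, and camera gave an adjusted p of 0.316. Every mutant array had a lower list mean than every wild-type array. The gap was smaller than the rounding, with mutant replicate 2 and wild-type replicate 1 both at 9.07. Of the 27 lists, 3 were apart in this way, where 10% would be by chance. With the mean of a gene's probe sets the lens epithelium list was called lower, with a mean difference of -0.24 and an adjusted p of 0.0424. Its adjusted p was 0.514 with an estimated correlation. The list of epithelial junction genes, which also holds Cdh1, had a mean of 0.07 over 19 genes (adjusted p = 0.638), with Epcam at 0.55 ± 0.24, and the list of integrins a mean of -0.18 over 13 genes (adjusted p = 0.138), with Itga3 at -0.72 ± 0.31 and Itga2 at -0.45 ± 0.28. Genes of the epithelial to mesenchymal transition had a mean of 0.23 over 19 genes, with the collagen Col1a1 at 1.32 ± 0.60 and Tnc at 0.48 ± 0.19. The difference of Col1a1 was 0.83 without mutant replicate 1, and also 0.83 without wild-type replicate 1. The camera adjusted p of this list was 0.104, and 0.501 with an estimated correlation. The list mean was 0.33 without mutant replicate 3 (adjusted p = 0.00749) and 0.19 with the mean of a gene's probe sets (adjusted p = 0.041).

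Cell division genes rose as a list. The 18 measured members had a mean log2 difference of 0.48, with 15 higher and 3 lower. Nusap1, a spindle protein, was at 9.43 ± 0.46 in mutants and 8.51 ± 0.19 in wild types, and Cenpf, a kinetochore protein, at 5.96 ± 0.32 and 5.04 ± 0.52 (log2, SD, n = 3). Camera gave an adjusted p of 4.69e-05 with the preset correlation, and the adjusted p was 0.501 with an estimated correlation. With array weights the mean was 0.13 and the adjusted p 0.232, and 0 members passed over all genes or adjusted over the list alone. DNA replication genes had a mean of 0.24 over 17 genes, 15 of them higher, with Pcna at 0.85 ± 0.50 (0.32 without wild-type replicate 1) and Gins1 at 0.43 ± 0.28 (SE). Their adjusted p was 0.0606, and 0.692 with an estimated correlation. The list mean was 0.46 without mutant replicate 3 (adjusted p = 2.17e-05) and 0.29 without wild-type replicate 1 (adjusted p = 0.0259). With all arrays the list was called with the replicate number as a block (0.0436), median centring (0.0431), a trended prior (0.0486) and the mean of a gene's probe sets (0.0356).

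The BMP and TGF-beta response list, which also holds ligands such as Tgfb2 and Bmp7, rose by a mean log2 of 0.41, with 14 of 16 higher. Id4, an inhibitor of basic helix-loop-helix factors, was at 9.04 ± 0.20 in mutants and 8.08 ± 0.91 in wild types (SD, n = 3). Ccn2, a matricellular protein, was at 10.67 ± 0.69 and 9.99 ± 0.21. Its difference was 0.68 with all arrays and 0.28 without mutant replicate 3. Camera gave an adjusted p of 0.0133 with the preset correlation, and the adjusted p was 0.514 with an estimated correlation; 0 members passed over all genes or adjusted over the list alone. The call ended when single arrays were left out: without wild-type replicate 1 the mean was 0.06 (adjusted p = 0.959) and the difference of Id4 0.46, and without mutant replicate 2 it was 0.34 (adjusted p = 0.104). With all arrays kept, array weights also ended it (mean 0.04, adjusted p = 0.898).

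Markers of cells outside the lens were measured in the same arrays. Macrophage and leukocyte genes rose as a list, with a mean log2 difference of 0.72 and all 16 members higher. The leukocyte phosphatase Ptprc was at 4.44 ± 0.70 in mutants and 3.36 ± 0.13 in wild types, and the lysosomal protein Cd68 at 4.79 ± 0.73 and 3.89 ± 0.20 (SD, n = 3), both dimmer than the median probe set. Camera gave an adjusted p of 5.05e-06 with the preset correlation, and the adjusted p was 0.501 with an estimated correlation. Mutant replicate 2 had a list mean of 7.12, against 5.59 and 5.98 in the other mutants and 5.43 to 5.60 in the wild types, and without it the mean difference was 0.28 (adjusted p = 0.0249).

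Genes of the retina and its pigment epithelium rose by a mean log2 of 0.45, with 13 of 16 higher. The melanocyte and pigment cell genes Pmel and Dct had the lowest p, Pmel at 7.05 ± 0.22 against 6.31 ± 0.33 and Dct at 7.44 ± 0.47 against 6.40 ± 0.65 (SD, n = 3). Genes of the corneal stroma and periocular mesenchyme rose by a mean of 0.35, with 10 of 14 higher, and with the lowest p for Col6a1 and the fibrillar collagen Col5a2, at 7.25 ± 0.38 against 6.58 ± 0.39. Camera gave adjusted p of 0.00599 for the retina list and 0.0305 for the stroma list with the preset correlation, and an adjusted p of 0.374 for both with an estimated correlation. Over all genes 0 members passed in the macrophage, retina and stroma lists; adjusted over the list alone, 1 stroma gene (Col6a1) did. The retina call ended without wild-type replicate 1 (mean 0.32, adjusted p = 0.0529) and without mutant replicate 1 (mean 0.38, adjusted p = 0.0826). The stroma call ended without wild-type replicate 1 (mean 0.25, adjusted p = 0.361), wild-type replicate 3 (mean 0.34, adjusted p = 0.0813) or mutant replicate 1 (mean 0.21, adjusted p = 0.207). Array weights ended both calls (mean 0.26 and adjusted p = 0.232 for retina, mean 0.36 and adjusted p = 0.117 for stroma), and the stroma call, with 6 of 14 members brighter than the median probe set, also ended with dim probe sets left out (mean 0.30, adjusted p = 0.184) and with the mean of a gene's probe sets (mean 0.25, adjusted p = 0.0595). With wild-type replicate 1 and mutant replicate 2 both left out, the mean of each list was 0.26, and the adjusted p was 0.269 for stroma and 0.133 for retina.

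Markers of other neighbouring tissues passed no list test. Blood vessel endothelium had a mean log2 difference of -0.17 (camera adjusted p = 0.452), with Pecam1 at -0.49 ± 0.35 and Cldn5 at -0.58 ± 0.44 (SE). Corneal and skin epithelium had a mean of 0.03 (0.667), with Krt14 at 0.29 ± 0.19 and Krt1 at -0.46 ± 0.34, and 2 of its 18 members were brighter than the median probe set. Skeletal muscle had a mean of -0.04 (0.638), with Acta1 at -0.48 ± 0.25 and Tnnc2 at -0.27 ± 0.20, and 0 of 12 members brighter than the median probe set. Erythroid genes had a mean of 0.23 and a median of -0.09, and camera placed them downward (adjusted p = 0.9), with Alas2 at 1.15 ± 1.44 and Epb42 at -0.19 ± 0.17. Alpha-globin signal differed widely between arrays of both groups, at log2 levels of 12.6, 7.06 and 10.44 in mutants and 11.98, 7.78 and 6.74 in wild types. The Y-linked gene Eif2s3y was at 10.30 ± 0.04 in mutants and 10.31 ± 0.47 in wild types (SD, n = 3), Kdm5d at 7.63 ± 0.09 and 7.69 ± 0.24, Uty differed by 0.20 ± 0.19, and Xist, the RNA of the inactive X chromosome, was at or below 4.34 on its brightest probe set in every array. The sex-linked list had a mean of 0.07 (adjusted p = 0.638). It joins Xist with Y-linked genes, which a difference in sex would move in opposite directions, so its mean cannot show one.

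The remaining pathway lists were not called with the settings used throughout. Endoplasmic reticulum stress genes had a mean log2 difference of 0.39 and a camera adjusted p of 0.0591, with Chac1 at 1.95 ± 1.24 and the chaperone Hspa5 at 0.35 ± 0.22 (SE); Chac1 was at 8.15 in mutant replicate 3, and without that array its difference was 0.45. The list mean was 0.55 without mutant replicate 1 (adjusted p = 0.0232) and 0.57 without wild-type replicate 3 (adjusted p = 0.0054). With all arrays the list was called with the replicate number as a block (0.0127), median centring (0.0385), a trended prior (0.0446) and the mean of a gene's probe sets (0.0374), and its adjusted p was 0.514 with an estimated correlation. Notch pathway genes had a mean of 0.29 (0.225), with Notch3 at -0.57 ± 0.27 and Notch1 at 0.77 ± 0.46 (0.22 without wild-type replicate 1). Immediate early and heat shock genes had a mean of 0.25 (0.173), with Hspa1b at 1.24 ± 0.57 (0.58 without wild-type replicate 1) and Egr2 at 1.26 ± 0.62 (0.54 without mutant replicate 2). For p53 targets the mean was 0.21 (0.579), with Fas at -0.61 ± 0.30 and Cdkn1a at 0.66 ± 0.35, and for Wnt pathway genes 0.09 (0.638), with Sfrp2 at 1.31 ± 0.53 and Sp5 at -0.31 ± 0.24. FGF and ERK response genes had a mean of 0.11 (0.638), with Spred1 at 0.45 ± 0.39 and Spry2 at 0.65 ± 0.72, and without wild-type replicate 1 Spry2 was at -0.22 and the list mean was -0.32 with an adjusted p of 0.0436; with all arrays and an estimated correlation the adjusted p was 0.776. Cholesterol synthesis genes had a mean of -0.13 (0.452), with Mvk at -0.44 ± 0.19 and Mvd at -0.51 ± 0.52. The difference of Mvd was 0 without wild-type replicate 1 and -1.08 without wild-type replicate 2. Glutathione and oxidative stress genes had a mean of 0.01 and a median of 0.11 where camera gave a downward direction (adjusted p = 0.638); Gstm1 passed adjusted over the list alone, as 1 of 17 genes, and Cat was at -0.49 ± 0.20.

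Of the 27 lists, 8 were called by limma camera with the preset correlation, 6 higher and 2 lower in mutants. With an estimated correlation 0 were called, with a lowest adjusted p of 0.374, and limma's rotation test fry called 0. The estimated correlations of the 8 lists ran from 0.02 (stroma) to 0.52 (macrophages), above the preset 0.01. Camera with the preset correlation also called 8 lists when mutant replicates 1 and 2 with wild-type replicate 2 were set against the rest. The count of 8 therefore does not set mutants apart from wild types.

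**Figure D3:**
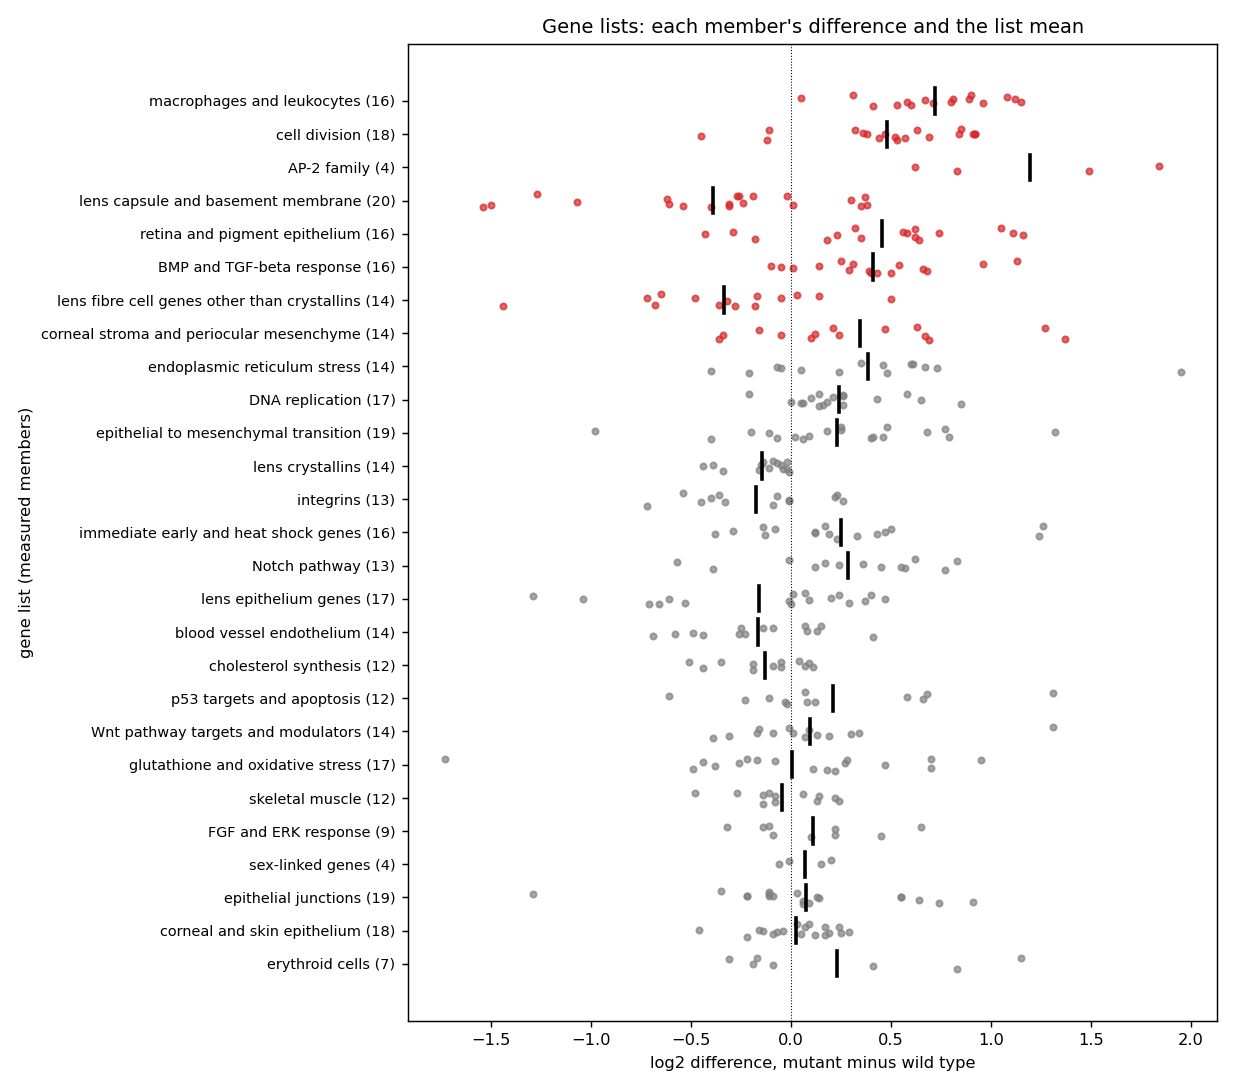
Log2 difference, mutant minus wild type (horizontal axis), of each measured member of the 27 gene lists (vertical axis, number of measured members in brackets), with 1 point per gene and a black line at the list mean. Red points mark the 8 lists called with the preset correlation, of which the AP-2 family has the highest mean, 1.19, and the capsule list the lowest, -0.39; with an estimated correlation 0 lists were called.

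**Figure D4:**
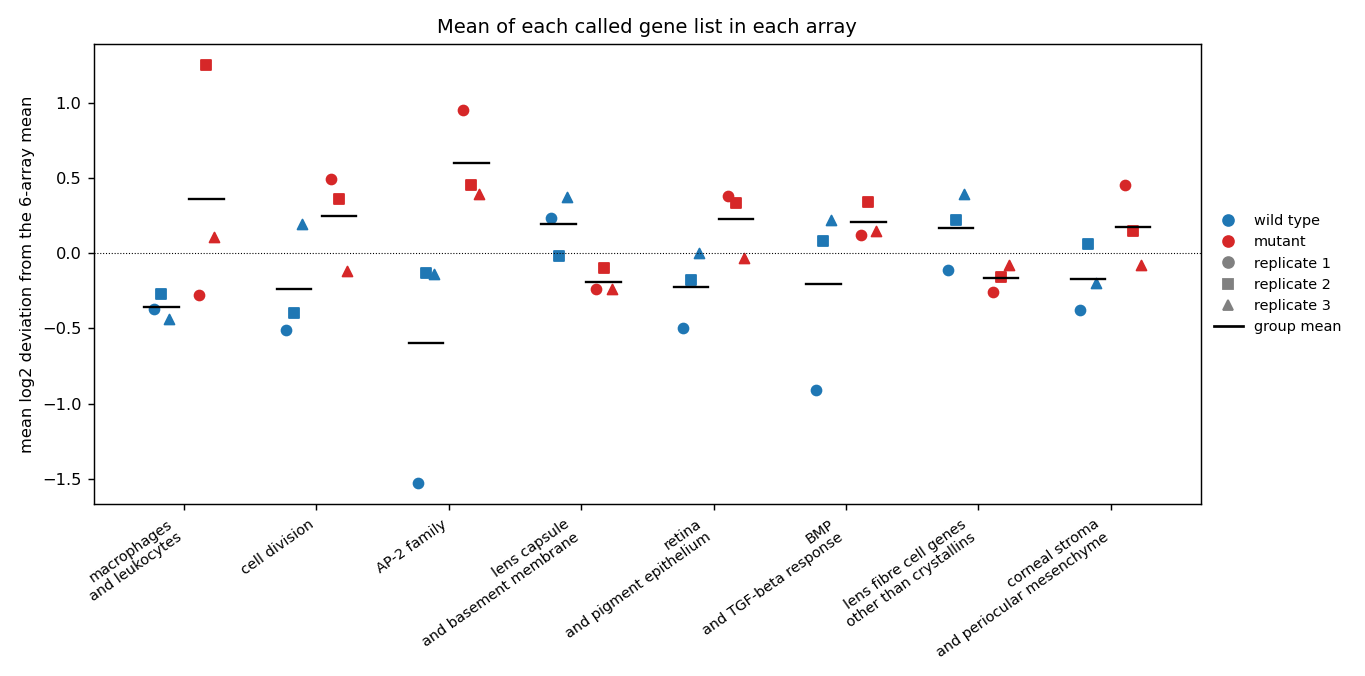
Mean over the members of each of the 8 called lists (horizontal axis) in each array, as the log2 deviation from the mean of the 6 arrays (vertical axis), with 1 point per array, marker shape for the replicate number and a line at the group mean. All mutant arrays lie apart from all wild-type arrays in 2 of these lists, AP-2 family and capsule; mutant replicate 2 is far above the rest for macrophages, and wild-type replicate 1 far below for the AP-2 and BMP lists.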

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

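The alternatives that leave out wild-type replicate 1 and mutant replicate 2 together, or take the 3' to 5' difference of control probe sets as a covariate, were chosen after seeing the data. The count of 0 probe sets and 0 genes held under every alternative except array weights, which called 7 probe sets and 5 genes; unadjusted counts ran from 495 to 3397 of the 22626 probe sets against 742, and the count was 255 of 11313 with dim probe sets left out. The number of lists called was 8, between 7 and 10 when 1 array was left out, 6 with both arrays left out, and up to 11 elsewhere, but 5 with array weights, 0 with an estimated correlation and 0 with fry. With the replicate number as a block, 0 probe sets and 10 lists were called. Same-numbered samples deviated with correlations of -0.07, -0.26 and -0.16, and no sample correlated best with its own number. These values give no sign of pairing. With so few arrays they cannot show whether a number marks a litter, and the labels do not say. Tfap2a stayed higher in mutants, by 0.19 (array weights) to 0.87 (without wild-type replicate 3).

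Differences that changed sign follow; causes were not tested. With 1 array left out, Pax6 ran from -0.07 to 0.85, erythroid genes from -0.14 to 0.65, p53 targets from -0.09 to 0.43, FGF response from -0.32 to 0.34, Notch from -0.05 to 0.48, cholesterol synthesis from -0.26 to 0.06 and sex-linked genes from -0.07 to 0.17. With both arrays left out, Pax6 was -0.12, p53 targets -0.02, FGF response -0.34, BMP response -0.01, Notch -0.07, immediate early genes -0.04, cholesterol synthesis 0.01 and sex-linked genes -0.12. With array weights FGF response was -0.26. Genes whose difference lay within 1 standard error of 0 also changed sign under 1 or more alternatives, the farthest being Cdh2 (-0.31) and Spry2 (-0.22) without wild-type replicate 1, Prox1 (0.14) without mutant replicate 1, Xist (-0.27) without mutant replicate 2, Eif2s3y (0.14) and Kdm5d (0.07) without wild-type replicate 2 and Maf (0.14) with array weights. Leaving out 1 array moved the difference by over 1.5 times or turned its sign for 42 of 79 named genes. Among them, it did so for 0 of the 20 of lowest p. Those 20 were chosen by their p on these same arrays, so such stability is built into the choice. Of the list results, 33 lost their call in the same direction under an alternative, the BMP list lost its call with both arrays left out as its sign changed, and 18 gained a call in the same direction; among the latter, crystallins had an adjusted p of 0.00601 with array weights. Background is not measured separately in the deposited values, so small differences of dim probe sets are limited by it.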

Other observations

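The lists of neuronal and neural retina genes, and the tests of wild-type replicate 1 for whole-transcript levels, RNA degradation and blood and of the macrophage genes, were chosen after the results they bear on were seen. Genes of neurons had higher values in the mutant lenses as a group. Of 35 measured genes in a list that left out the neuronal genes already seen among those of lowest p, 30 were higher and 5 lower, with a mean log2 difference of 0.70. Among them were the axon growth protein Gap43 (1.73), the microtubule proteins Mapt (1.46), Tubb3 (1.28) and Dcx (1.90), and Crmp1 (1.80), each with a limma adjusted p of 0.999. The list means were 6.88, 6.56 and 6.33 in mutants and 5.66, 5.95 and 6.07 in wild types, each mutant above each wild type, and an exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow.

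A hypothesis from these values is that the mutant lenses may have carried more neuronal RNA or expressed more neuronal genes. Camera with an estimated correlation gave p = 0.0149 for the list, 0.0297 adjusted over these 2 lists and 0.335 adjusted together with the lists set before, 29 in all; with 1 array left out p ran from 0.0181 to 0.0578, the highest without wild-type replicate 2. Low signal in wild-type replicate 1 alone stays open: without it the mean was 0.58, which passed the bound set for excluding it by less than its standard error across genes, a margin asked for only once the value was known. For retina carried over with the lens, 20 neural retina genes had a mean of 0.29 and a median of 0.05, the mean below the neuronal one by 0.41 ± 0.16 (SE across genes); it was 0.12 without wild-type replicate 1 and 0.53 without wild-type replicate 3, where camera with an estimated correlation gave p = 0.0337, against 0.472 with all arrays. A gap of over 2 SE had been set to exclude it, although an SE across genes leaves out the spread between arrays. That was wrong because only 4 of the 20 genes were brighter than the median probe set. Of those 4, Isl1 (1.89), Prdm1 (1.11) and Rorb (0.76) were higher in mutants and Sag (-0.20) was lower. The retina and pigment epithelium list set before, with 10 of 16 members brighter than the median probe set, had a mean of 0.45. Of its members 13 were higher and 3 lower, and camera with an estimated correlation gave an adjusted p of 0.374. Retinal RNA and neuronal expression in the lens therefore cannot be told apart.

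Wild-type replicate 1 stood apart along the first principal component, which held 53.9% of the variance. Differences in levels of whole transcripts are argued against as its whole cause, since the part of the deviations that a gene's pair of brightest probe sets did not share had an SD of 0.84 over 2364 genes, against 0.30 to 0.33 in the other arrays. A general loss of 5' signal is argued against too: the log2 difference of 3' over 5' beta-actin signal was 1.54 and that of Gapdh 1.07, inside the range of the other arrays. Blood is argued against by mutant replicate 1, which had more alpha-globin signal and still correlated with the remaining arrays at 0.981. Signal altered on some probe sets of a gene and not on others may account for part of the pattern, given the unshared SD. The correlation between a gene's probe sets was 0.39 ± 0.02 (SE) against 0.43 to 0.60. The gap to the nearest array is small, and the reading of this test was settled only once the value was known. Both probe sets were off by more than 2-fold in 330 genes, against 13 to 41 elsewhere. Of the 330, 11.2% had them off in opposite directions, against at most 3.85% elsewhere. This share adds no support: a 2-fold cut is below the log2 SD of the deviations here (1.07) and above it elsewhere (0.4 to 0.49). Most of the 330 were off in the same direction, so differences in whole transcripts may account for another part. What altered the signal stays open, and beyond transcript levels and blood no biological explanation was tested.

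Macrophage and leukocyte genes were highest in mutant replicate 2. More macrophage RNA in that sample alone may account for the list's shift: the other mutants together exceeded the wild-type mean by 0.28, with a wild-type SD of 0.09, but only 1 of them lay above every wild type. The test decides neither way, and an effect of the mutation on macrophages stays open as untested.

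Other splits of the 6 arrays into 3 and 3 make 10 in all, too few for a share under 0.05. For probe sets the real split called 0 and the highest other 0, so that all 10 gave as many; for genes the counts were also 0 and 0, again in 10 of 10. For lists the real split called 8 and the highest other 8, and 2 of the 10 splits gave as many. The split of mutant replicates 1 and 3 with wild-type replicate 2 against the rest had 2358 probe sets at an unadjusted p under 0.05, against 742 in the real one. It called 0 probe sets and 0 lists. This split keeps mutant replicate 2 and wild-type replicate 3 together. They lay at -45.1 and -32.5 on the second principal component (17.4% of the variance), with the other arrays at 9.66 to 28. Their 3' to 5' differences of beta-actin, 2.16 and 2.17, were the highest, against 1.24 to 1.79 elsewhere. Whether this accounts for the count was not tested.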
